A study of Mus musculus with 2 samples.

How the data were processed

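Gene expression was measured in liver and in adipose tissue of male C57BL/6J mice that had been given a normal diet or a high-fat diet for 4 weeks. Per the labels, RNA from 10 livers and 10 fat samples was pooled by diet. Whether each pool held 10 animals or fewer, which fat depot was taken and whether both tissues came from the same mice is not given in the sources used here. Each tissue was measured on 1 Agilent array with 2 channels, with the normal-diet pool in green (Cy3) and the high-fat pool in red (Cy5). Per the labels, cDNA was labelled directly during reverse transcription from an oligo-dT type primer. The direction of every ratio, high-fat pool over normal-diet pool, follows from the dyes in the labels.

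The deposited scanner files give, for each of 44397 spots, the median pixel intensity of the spot and of its local background in each channel, without normalization. The deposited log ratio is the log10 of red over green after the scanner software's own background subtraction and dye normalization, and its error is on the log10 scale too. The software set that ratio to 0 for 7732 spots of the liver array and 6996 of the adipose array. Per the file headers, images were read with Agilent Feature Extraction 11.5.1.1 and protocol GE2_1105_Oct12, while the submitters' processing notes name version 8.5.1.1. Mean signals had been planned as input, but the files used here hold median signals, which were taken in their place.

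Background was corrected with limma 3.58.1 in R 4.3.3 (normexp with an offset of 50, on all spots), and each array was normalized by loess with control spots at weight 0. A first liver fit was distorted by a few local backgrounds of up to 132254 in red and 54510 in green, against medians of 48 and 28. After that fit was seen, local backgrounds that the software marks as outliers were replaced on both arrays by the median of the array and channel (1602 red and 665 green spots in liver, 1480 and 406 in adipose tissue). The values with all local backgrounds as deposited are kept as an alternative, which gives 20 genes at least 2-fold higher and 35 lower in liver. Spots of one probe and then probes of one gene were averaged on the log2 scale. A probe was measured when it was well above background in both channels and its spots were not marked as outliers. Such marks took out 184 spots in liver and 213 in adipose tissue, and no spot was saturated. Of 39429 probes, 27508 matched 1 gene of the reference annotation through their transcript accession, for 20886 genes. Probes without a gene were counted as other transcripts and are not named. The arrays' annotation is of an older genome build (mm9) than the reference, so no positions are given.

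There was no replicate array and no dye swap, so no spread between animals and no p-value can be had, and a dye effect of a probe cannot be separated from the diet. A fixed rule of size was used instead: a gene was called higher or lower at a ratio of at least 2-fold. Where a gene was well above background in 1 channel only, its ratio is a bound, its brighter channel over its dim channel after loess. The dim channel was set to the higher of the gene's own signal and the lowest signal among probes well above background there. These bounds are open to dye bias without swaps. For the bounds and all log2 levels of a channel, the mean intensities of the 2 arrays were given the same distribution (Aquantile in limma). That step leaves the ratios unchanged. Levels compared between the tissues therefore assume that brightness is distributed alike on both arrays. For 39 gene lists (25 pathways and 14 sets of cell type markers), the median ratio of the measured members was set among the medians of 10000 random lists of the same size, drawn with replacement within 20 bins of brightness. A list with at least 5 measured members stood apart below percentile 2.5 or above 97.5. The percentile describes the list among other genes of the array and is not a test across animals. Members of a list are co-regulated, so real lists stand apart more readily than random ones.

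Genes were named by a rule: per tissue the 12 highest and 12 lowest genes with a full gene symbol, probes of one sign and a ratio over 2 times the scanner error, the 3 largest bounds each way, and the 4 members of each list with the largest ratio in either direction. Between tissues the rule took the 8 genes farthest from 0 the same way and the 8 that differed most in opposite ways. Some genes that the rule takes are not reported here. The lists, the rule, the size threshold and 9 alternatives were fixed before the data were examined. The alternatives were the software's log ratio, no background subtraction, an offset of 10, median centring, a looser filter on dim probes, no such filter, no saturated spot, the brightest probe per gene, and a ratio over 2 times the scanner error. Another 3 alternatives were chosen after seeing the data: all local backgrounds as deposited, leaving out genes of other tissues, and subtracting the running median of the ratio over genes of like brightness. Leaving out genes of other tissues removed 93 genes from the liver array and 883 from the adipose array: marker lists of other tissues, small intestine genes and, in adipose tissue, genes at least 4-fold brighter on the liver array.

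The processing was tested on simulated data. A simulated 2-fold difference was recovered at a median log2 ratio of 0.89 (liver) and 0.91 (adipose) upward and -0.85 and -0.84 downward, so 8% to 26% of such probes passed the 2-fold rule. A simulated 4-fold difference was recovered at 1.74 and 1.80 upward and -1.71 and -1.80 downward, and 96% to 100% of such probes passed. None of the unchanged simulated probes (0%) passed in either tissue. The simulated noise was smaller than the scanner software's error, extreme local backgrounds were capped and no dye bias of single probes was added. This share is therefore not the rate of false calls on the real arrays. Of 200 simulated random lists of 20 genes, 4% stood apart in each tissue, and of lists shifted by 1 standard deviation, 99.5% in liver and 100% in adipose tissue did. That shift was 0.27 in liver and 0.78 in adipose tissue, and smaller shifts were not simulated. The ratios were shuffled over genes first, so the simulation held no trend with brightness. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the lists, counts and plots. No DNA sequence was analysed.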

Results

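The series compares a normal diet with a high-fat diet in liver and in adipose tissue of male C57BL/6J mice after 4 weeks of feeding. Each tissue was measured on 1 array whose 2 channels held the RNA pools of the 2 diets. Of 39418 probes with a spot not marked as an outlier on the liver array, 23041 (58.5%) were well above background in both channels, and of 39427 on the adipose array 23189 (58.8%), which gave a ratio for 13642 and 14315 genes. In liver, 867 probes were above background in the high-fat channel alone and 790 in the normal-diet channel alone. In adipose tissue these numbers were 4188 and 520. The median spot signal was 93 (normal diet) and 127 (high fat) on the liver array, over local backgrounds of 28 and 48, and 97 and 274 on the adipose array, over 28 and 52.5. With 1 array per tissue the number of arrays limits the precision, and the scanner software's median error of a gene's log2 ratio was 0.21 in either tissue. Each tissue has a slide and scan of its own, so batch and tissue cannot be told apart. On the arrays, 29 of 29 hepatocyte markers were brighter on the liver array (median log2 difference 6.27) and 15 of 16 adipocyte markers on the adipose array (5.05). Ratios below are log2 of the high-fat pool over the normal-diet pool, without replicates. Members of a list named beyond the 4 with the largest ratios were chosen after their values were seen.

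The liver array asks which genes differ between livers of mice on the high-fat and on the normal diet. The gene with the highest ratio was Dbp, a transcription factor driven by the circadian clock, at 3.52 (11.4-fold). Genes of interferon defence and of the acute phase response were higher in the high-fat pool as groups, clock genes lay far apart in both directions, and markers of skeletal muscle were lower, as were 6 of 38 drug metabolism genes by at least 2-fold. In all, 67 of 13642 genes (0.491%) were at least 2-fold higher and 79 (0.579%) at least 2-fold lower, 8 and 6 of them at least 4-fold. A further 19 transcripts without a gene name were higher and 19 lower.

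Besides Dbp, the genes highest in the high-fat liver pool were Dmbt1 (2.98) and Tff3 (2.40), secreted proteins of mucosal surfaces, Cdh16 (2.37), a cadherin of kidney tubules, and Saa2 (2.19) and Saa1 (1.90), acute phase apolipoproteins. Cish, a feedback inhibitor of cytokine signalling, was higher by 2.13, Slc22a7, a transporter of organic anions, by 2.03, and Akr1c18, which inactivates progesterone, by 2.00. Fam171b (1.99), Trim54 (1.97), a ubiquitin ligase of striated muscle, and Tenm4 (1.95), a teneurin, followed. Of these, Cdh16, Akr1c18, Fam171b, Trim54 and Tenm4 each rest on 1 probe with a normal-diet log2 level of 6.90 to 7.46. The lowest such level among probes well above background was 6.19, so these ratios are sensitive to the background correction. The same holds for Moxd1 (7.01) and Ier5 (6.92) in the liver lists below, each on 1 probe. It also holds for the liver ratio of Cxcl13, on 1 probe at 6.68 in the high-fat channel, where the lowest such level was 6.37. The lowest were Zbtb16 (-2.73), a transcriptional repressor, and Cdkn1a (-2.68), the cell cycle inhibitor p21. Bcl6, another repressor, was at -1.98 and Arntl, which encodes the clock activator BMAL1, at -1.95. Enzymes of drug and sterol metabolism made up much of the rest: Cyp3a16 (-2.17), Cyp3a41b (-2.04), Cyp3a11 (-2.02), Gsta2 (-1.88), Cyp39a1 (-1.83) and Cyp2b10 (-1.83). Cyp3a genes are very similar in sequence, so their probes can bind each other's transcripts. The Cyp3a ratios here and in the lists may therefore not be separate observations. Ddit4, an inhibitor of mTORC1, and Bax, an effector of apoptosis, were both at -1.61. Among genes above background in 1 channel only, 45 were higher by a bound of at least 2-fold and 1 lower. The largest bounds were at least 7.36-fold higher for Ppef2, 6.55-fold for Shc3 and 6.38-fold for Nmrk2, and at least 2.11-fold lower for Adra2a, 1.60-fold for Perm1 and 1.44-fold for Cd27.

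Interferon response genes were higher as a group. Their 34 measured members had a median of 0.57, above all 10000 random lists, with 3 at least 2-fold higher (Ifit1 1.29, Gbp3 1.18, Usp18 1.15) and 1 lower (Bst2 -1.02). The 31 acute phase genes had a median of 0.40, also above all random lists, with Saa2 and Saa1 past 2-fold and Hamp, which encodes the iron hormone hepcidin, at 0.94. The 19 clock genes had a median of 0.35, above all random lists. Of these, 6 were at least 2-fold higher, among them Dbp, Wee1 (1.46) and Usp2 (1.43), and 2 lower, Arntl and Tsc22d3 (-1.29). Immediate early genes had a median of 0.15 over 26 members (percentile 99.9), with Ier5 (1.27), Nr4a1 (1.22) and Fos (1.11) higher and Gadd45b (-1.14) lower. MHC class II genes had a median of 0.29 over 11 members (percentile 99.98) and macrophage markers 0.15 over 27 (percentile 99.9), with none past 2-fold. H2-Aa was at 0.55 and Trem2, a lipid-sensing receptor of macrophages, at 0.78. Extracellular matrix genes had a small median of 0.09 over 38 members (percentile 98.3), none past 2-fold.

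Some lists of lipid genes stood apart upward by small amounts. The 27 genes of cholesterol synthesis had a median of 0.16 (percentile 99.9), with Idi1 (1.09) past 2-fold and Sqle, which makes squalene epoxide, at 0.78. The 41 genes of fatty acid oxidation and PPARalpha targets had a median of 0.21 (percentile 99.97), with Fabp1 at 0.97. Pdk4, which restrains glucose oxidation, was lower (-1.48). Skeletal muscle markers were lower on the same array too (median -1.10), and the source of the Pdk4 ratio was not tested. The 23 lipoprotein genes had a median of 0.24 (percentile 99.9), with Apoe (1.15) and Apoa2 (1.14) past 2-fold. Bile acid and sterol transport genes had a median of 0.15 over 25 members (percentile 99.1), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, higher (1.40) and Nr0b2, a repressor of that gene, lower (-1.38). The 21 male-biased liver genes had a median of 0.29 (percentile 99.99), with Hsd3b5 (1.89), Moxd1 (1.73) and Nudt7 (1.32) higher and Elovl3 (-1.39) lower. The 29 hepatocyte markers, abundant liver transcripts, had a median of 0.38 themselves (percentile 99.99), with Cyp2e1 (1.14) and Apoa2 past 2-fold. Genes of any kind at a mean log2 intensity of 16 to 17 had a median of 0.26 (107 genes) and those at 17 to 18 of 0.61 (50 genes). Apoe and Apoa2 lay at log2 levels of 16.7 in the normal-diet channel and 17.9 in the high-fat channel. Fabp1 lay at 16.4 and 17.4 and Cyp2e1 at 16.2 and 17.3. For genes this bright, the ratio cannot be separated from that trend. The calls for hepatocyte, male-biased, bile acid and matrix genes ended with the software's log ratio (percentiles 66.9, 83.4, 89.2 and 96.2) and with the running median by brightness subtracted (52.1, 91.1, 82.9 and 94.7).

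The drug metabolism list lay slightly lower. Of 38 measured, 6 were at least 2-fold lower, among them Cyp3a16, Cyp3a11, Gsta2 and Cyp2b10, and 1 higher, Cyp2e1, with a median of -0.07 (percentile 1.23). NRF2 targets had a median of -0.08 over 25 members (percentile 2.11), and its only member past 2-fold, Hmox1 (-1.29), averages 2 probes that disagree, 1 at -2.59 and 1 near 0. Heat shock proteins had a median of -0.25 over 19 members, below all random lists, with none past 2-fold and Bag3 at -0.61. Ribosomal proteins had a median of -0.07 over 41 members (percentile 0.5), with none past 2-fold. Skeletal muscle markers, of a tissue the labels do not name, were the group farthest from 0. Of 26 measured, 16 were at least 2-fold lower, among them Myh4 (-1.60), Tnni2 (-1.59), Myh7 (-1.53) and Tcap (-1.52), and the median was -1.10. The thermogenic list moved with them, at a median of -0.13 over 18 members (percentile 0.36), with Elovl3 and the muscle-expressed Cox8b (-1.14) past 2-fold.

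Over the 1377 liver genes past 2 times the scanner error, the calls ended for fatty acid oxidation (percentile 67.3), lipoproteins (78.8), acute phase (79.6), macrophages (73.2), NRF2 targets (29.6), heat shock proteins (5.2), male-biased genes (84.5), bile acid genes (35.4) and hepatocyte markers (47.4). This filter selects on the ratio itself, so the medians left were mostly farther from 0 (0.54 for fatty acid oxidation, 0.63 for lipoproteins, 0.51 for acute phase, -0.51 for heat shock proteins), and that of NRF2 targets changed sign (0.23 over 5 members). Without a filter on dim probes the calls ended for thermogenic genes (7.4), NRF2 targets (3.35) and matrix (71.1), with the brightest probe per gene for ribosomal proteins (3.85) and with local backgrounds as deposited for heat shock proteins (8.77).

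No shift was seen by this rule in the remaining liver lists. Fatty acid synthesis had a median of -0.07 (percentile 3.51), with Elovl3 and Tkt (-1.07) lower. Lipid droplet genes were at 0.09 (94.2), female-biased liver genes at 0.11 (93.9), with Cyp3a16 and Cyp2b10 lower, and gluconeogenesis genes at 0.08 (89.0), with Pdk4 and Slc2a4 (-1.07) lower. Skeletal muscle markers were at -1.10 on the same array, and the source of the Pdk4 and Slc2a4 ratios was not tested. Inflammatory mediators were at 0.07 (90.9), with members past 2-fold in both directions, among them Cxcl13 (-1.12). The unfolded protein response was at 0.01 (49.5), cell cycle genes at -0.01 (29.5), oxidative phosphorylation at -0.02 (4.67) and genes tied to fat-mass expansion at -0.03 (28.4). Among markers, adipocyte genes were at 0.03 (65.3), with Car3 (1.28) higher and Slc2a4 lower, and Kupffer cell genes at 0.06 (81.9), with Marco (-1.28) lower. The medians were 0.04 for T and NK cells (69.9), -0.08 for B and plasma cells (4.93), 0.06 for granulocytes and mast cells (76.5) and -0.06 for endothelium (6.30). They were 0.01 for fibroblasts and stellate cells (49.6), -0.02 for erythroid cells (33.9), -0.12 for the male reproductive tract (4.12), 0.02 for epithelium and mesothelium (57.6) and 0.04 for exocrine pancreas (65.6). In these 9 marker lists no member passed 2-fold.

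**Figure D1:**
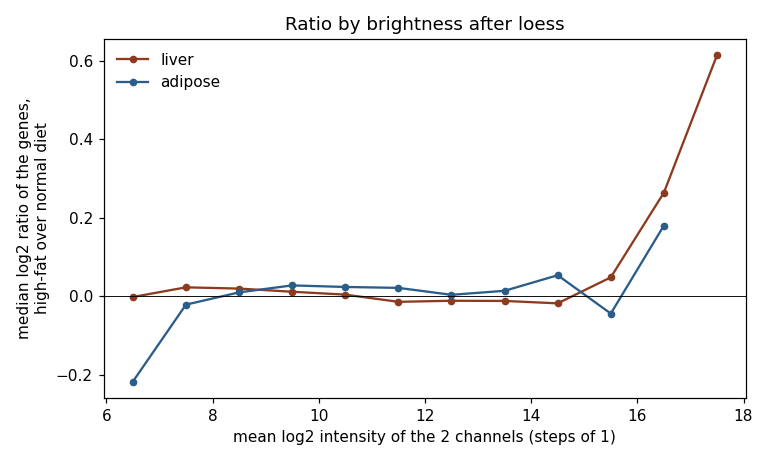
Median log2 ratio of the high-fat over the normal-diet pool (y axis) of genes in steps of mean log2 intensity of the 2 channels after loess (x axis), for liver and for adipose tissue. The liver medians stay near 0 up to an intensity of 16 and are 0.26 and 0.61 in the brightest steps, and the adipose medians range from -0.22 in the dimmest step to 0.18 in the brightest.

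**Figure D2:**
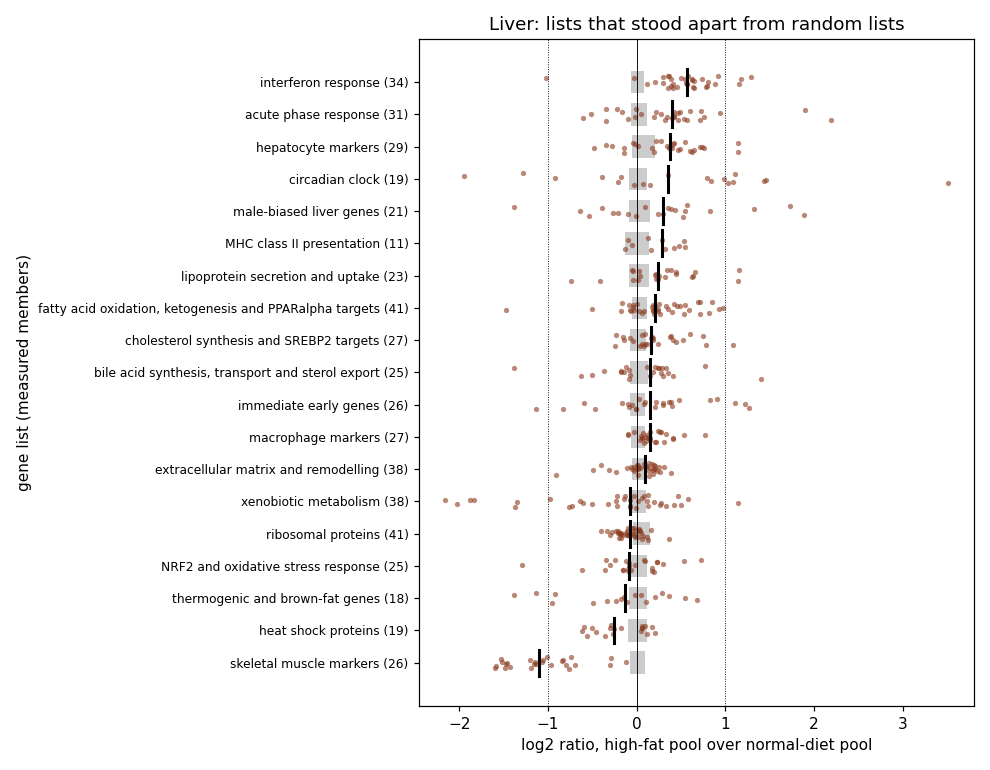
Log2 ratio of the high-fat over the normal-diet liver pool (x axis) for each measured member (points) of the gene lists that stood apart (y axis, number of measured members in brackets), with the list's median (black bar), the middle 95% of medians of random lists (grey) and 2-fold (dotted lines). Skeletal muscle markers lie farthest below 0 (median -1.10) and interferon genes farthest above (0.57), while clock genes spread from -1.95 to 3.52.

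The liver counts depend on the normalization. With median centring 445 genes were higher and 28 lower (94.1% of the 2-fold genes higher, against 45.9%), and the median of all measured genes was 0.32. Median centring subtracts the same constant from every log2 ratio of an array. A dye difference that changes with brightness therefore stays in these ratios. The medians of drug metabolism, NRF2, heat shock, ribosomal and thermogenic genes then lay above 0, and the calls for NRF2 (percentile 31.3) and matrix genes (86.3) ended. The counts were 138 and 157 with the software's log ratio, 20 and 35 with local backgrounds as deposited, 116 and 79 (59.5% higher) with probes above background in at least 1 channel, 103 and 78 (56.9%) without a filter on dim probes, and 65 and 62 without genes of other tissues.

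The adipose array asks the same question of fat. Its largest ratios belonged to genes of other organs. Genes of the small intestine, led by Fabp2, the fatty acid binding protein of enterocytes, at 6.42 (85.5-fold), were higher in the high-fat pool. Most hepatocyte markers, led by Ambp at -5.59, were lower (21 of 29 at least 2-fold lower and 3 higher). The list of cell division genes was higher in the high-fat pool as a group by a smaller amount (median 0.75, 10 of 31 past 2-fold). In all, 605 of 14315 genes (4.23%) were at least 2-fold higher and 735 (5.13%) at least 2-fold lower, 218 and 309 of them at least 4-fold, with 101 and 166 further transcripts without a gene name.

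The highest genes after Fabp2 were Reg3b (6.36) and Reg3g (5.28), antibacterial lectins of the gut, and the Paneth cell defensins Defa23 (5.80), Defa40 (5.80), Defa3 (5.72), Defa27 (5.65), Defa29 (5.42) and Defa42 (5.34). Sis, the sucrase-isomaltase of the brush border, was at 5.76, Clca1, secreted by goblet cells, at 5.46 and Mep1b, a brush-border protease, at 5.36. Defensins, Mup and Cyp3a genes form families of very similar sequence, so a probe for 1 member can bind transcripts of others. The lowest genes after Ambp were Cyp4a14 (-5.32), a fatty acid hydroxylase, and Fgg (-5.32), a fibrinogen chain. The urinary proteins Mup3 (-5.19), Mup20 (-5.13) and Mup5 (-4.72), made in liver, and the plasma proteins Serpinc1 (-4.93), Serpina3k (-4.88), Pzp (-4.85) and Apoh (-4.77) followed, with Slco1b2 (-4.73), a hepatocyte uptake transporter. Tex22, a testis gene, was at -4.77. Among genes above background in 1 channel only, 69 were higher by a bound of at least 2-fold and 64 lower. The largest bounds were at least 7.85-fold higher for Slc15a1, the intestinal peptide transporter, 7.18-fold for Slc13a1 and 6.81-fold for Ms4a18, and at least 9.49-fold lower for Lingo1, 7.17-fold for Fam71f1 and 5.09-fold for Cyp3a41b.

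Markers of other tissues were far apart in the adipose pools. Of 29 hepatocyte markers, 21 were at least 2-fold lower, among them Ambp, Serpinc1, Apoh and Hpx (-4.66), and 3 higher (Apoa1 2.08, Hnf4a 1.90, Apob 1.62, genes that the gut also expresses), with a median of -3.04, below all random lists. The male reproductive tract list had a median of -2.10, also below all, with 6 of 9 measured members lower, among them the sperm protamines Prm2 (-3.76) and Prm1 (-2.98) and the epididymal Crisp1 (-3.19). Exocrine pancreas markers had a median of -1.46, below all, with 16 of 23 lower, among them the digestive enzymes Try4 (-2.98) and Pnlip (-2.64) and Sycn (-2.79), and 2 higher (Spink1 5.01, Zg16 3.97), both of which the gut also makes. Skeletal muscle markers had a median of -0.58, below all, with 5 of 19 lower (Tnnc2 -3.29, Myh4 -3.19, Ckm -1.85, Tnni2 -1.49, Tnnt3 -1.48). Erythroid markers had a median of -0.44 over 7 members (percentile 1.03), none past 2-fold. A list of 47 small intestine genes, written after the intestinal genes above had been seen but before any value of its own members was, had 37 of 38 measured members at least 2-fold higher and a median of 3.24. Epithelial and mesothelial markers did not stand apart as a list (0.13, percentile 93.5), but the epithelial genes Cldn7 (2.89), Epcam (2.80), Krt8 (2.63), Cdh1 (2.17) and Krt19 (2.07) were higher and Elf5 (-1.67), Lrrn4 (-1.43) and Wt1 (-1.24) lower.

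Lists of genes that liver expresses moved with the hepatocyte markers (median -3.04). The 13 male-biased liver genes had a median of -2.39, below all random lists, with 9 lower, among them Mup3, Mup5, Serpina1e (-3.98) and Mup4 (-3.71). Drug metabolism genes had a median of -0.68, below all, with 12 of 33 lower, among them Cyp3a16 (-4.26), Cyp3a11 (-3.76) and Cyp2a4 (-3.00), and 3 higher (Cyp3a13 2.38, Nr1i2 1.12, Sult1d1 1.09). Female-biased liver genes had a median of -0.45 over 11 members (percentile 0.2), with Cyp3a16, Cyp2a4 and Fmo2 (-1.10) lower. Gluconeogenesis and insulin-responsive genes had a median of -0.30 over 27 (percentile 0.05), with Igfbp1 (-3.94), Tat (-2.51), Igfbp2 (-1.82) and Pdk4 (-1.08) lower and Gpt (1.27) higher. The 21 lipoprotein genes went both ways, with 7 lower, among them Apoc4 (-3.37), Apom (-3.28) and Apoa2 (-3.16), 5 higher, among them Apoa4 (3.15), Mttp (2.94), Apoa1 (2.08) and Apob (1.62), and a median of -0.33 (percentile 0.06). So did the 27 acute phase genes, with 9 lower, among them Fgg, Hpx and Fgb (-4.29), 5 higher (Saa2 3.95, Saa1 3.18, Lbp 1.64, Saa3 1.48, Orm1 1.07) and a median of -0.19 (percentile 1.27). The bile acid list did not stand apart (-0.15, percentile 6.8). Of its 19 measured members, 6 were higher, among them Slc51a (4.06) and Slc51b (3.66), which export bile acids from enterocytes, and 4 lower (Slco1b2, Slc27a5 -4.24, Abcb11 -2.25, Cyp7b1 -1.49).

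Genes of cell division were higher in the high-fat adipose pool, beside the intestinal genes (median 3.24) of a tissue that also holds dividing cells. Of 31 measured, 10 were at least 2-fold higher, among them the proliferation marker Mki67 (2.07), Cenpe (1.49), Ccnb2 (1.47) and Plk1 (1.27), and none lower, with a median of 0.75, above all random lists. B and plasma cell markers had a median of 0.54 over 12 members, above all, with Jchain, the joining chain of secreted antibody, at 1.91. T and NK cell markers had a median of 0.16 over 18 (percentile 98.0), with Gzma (1.17) and Ccr7 (1.13) higher. Interferon response genes had a median of 0.23 over 33 (percentile 99.7), with Oasl1 (1.41) past 2-fold. These immune groups too moved beside the intestinal genes.

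Lists of matrix, fat-mass and lipid genes differed less, and they too moved beside the intestinal genes (median 3.24). Extracellular matrix genes had a median of 0.37 over 46 members, above all random lists, with Fbn1 (2.09), Tgfbi (1.18), Col6a3 (1.17) and Sparc (1.07) higher and Bgn (-1.07) lower. Genes tied to fat-mass expansion had a median of 0.30 over 19 (percentile 99.4), with Mest (1.86), the hormone gene Lep (1.66), Sfrp5 (1.59) and Npr3 (1.39) higher. Cholesterol synthesis had a median of 0.35 over 26 (percentile 99.98), with Stard4 (1.78) among the genes higher. Fatty acid synthesis had a median of 0.26 over 25 (percentile 99.6), with Fasn (1.16) higher and Elovl3 (-2.51), Acacb (-1.11) and Fads1 (-1.001) lower. Lipid droplet genes had a median of 0.25 over 25 (percentile 98.9), with Dgat2 (1.89), Cideb (1.45) and Fabp5 (1.40) higher. Adipocyte markers did not stand apart (0.16, percentile 89.6), with Lep higher and Cfd, which encodes adipsin, lower (-1.70).

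Over the 4476 adipose genes past 2 times the scanner error, the calls ended for matrix (percentile 96.9), fat-mass expansion (96.6), cholesterol synthesis (96.1), fatty acid synthesis (94.4), lipid droplets (90.7), interferon response (92.0), B and plasma cells (97.1), erythroid cells (6.84) and female-biased liver genes (3.64). Here too the medians left were farther from 0, among them 0.56 for matrix, 0.66 for fat-mass expansion, 0.60 for cholesterol synthesis and 0.59 for lipid droplets. Without a filter on dim probes they ended for T and NK cells (93.4) and erythroid cells (9.15), and for the acute phase list with the software's log ratio (4.55) and with an offset of 10 (5.83).

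No shift was seen by this rule in the remaining adipose lists. The pools also differed in intestinal genes (median 3.24) and male reproductive tract markers (-2.10). The tissue that gave rise to the ratios of single members below was not tested. Fatty acid oxidation genes were at -0.07 (percentile 10.5), with 6 of 41 lower, among them Cyp4a14, Cyp4a31 (-3.87) and Cyp4a10 (-3.14), and Creb3l3 (1.91) higher. Thermogenic genes were at -0.17 (4.09), with 6 of 21 lower, among them Kng2 (-3.29), Cited1 (-3.06), Slc27a2 (-2.58) and Elovl3, and Cox7a1 (1.80), Gk (1.31) and Acot11 (1.16) higher. Inflammatory mediators were at 0.02 (58.6), with Nos2 (3.12), Ccl8 (2.20), Ccl2 (1.47) and Ccl7 (1.38) higher and Ptgs2 (-3.68) and Cxcl13 (-1.14) lower. NRF2 targets were at 0.06 (64.9), with Gpx2 (3.46), an intestinal glutathione peroxidase, and Srxn1 (1.23) higher and Gpx3 (-1.75) lower. Clock genes were at -0.08 (17.1), with Hlf (-1.11) lower. Immediate early genes were at 0.11 (87.7), with Rgs1 (1.14) higher and Gadd45g lower (-1.09, but 0.10 with median centring). MHC class II genes were at 0.24 (96.1), with Ctss (1.08) higher, and macrophage markers at 0.15 (96.0), with Lgals3 (1.08) higher. Fibroblast markers were at 0.12 (86.8), with Dpp4 (2.23) higher and Clec3b (-1.38) and Des (-1.17) lower, and granulocyte and mast cell markers at -0.26 (6.80), with S100a8 (1.51) higher. With no member past 2-fold, oxidative phosphorylation was at 0.14 (94.9), the unfolded protein response at 0.02 (51.0), heat shock proteins at -0.15 (6.68), ribosomal proteins at -0.04 (19.1), Kupffer cell markers at -0.08 (36.8) and endothelial markers at 0.06 (71.2).

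**Figure D3:**
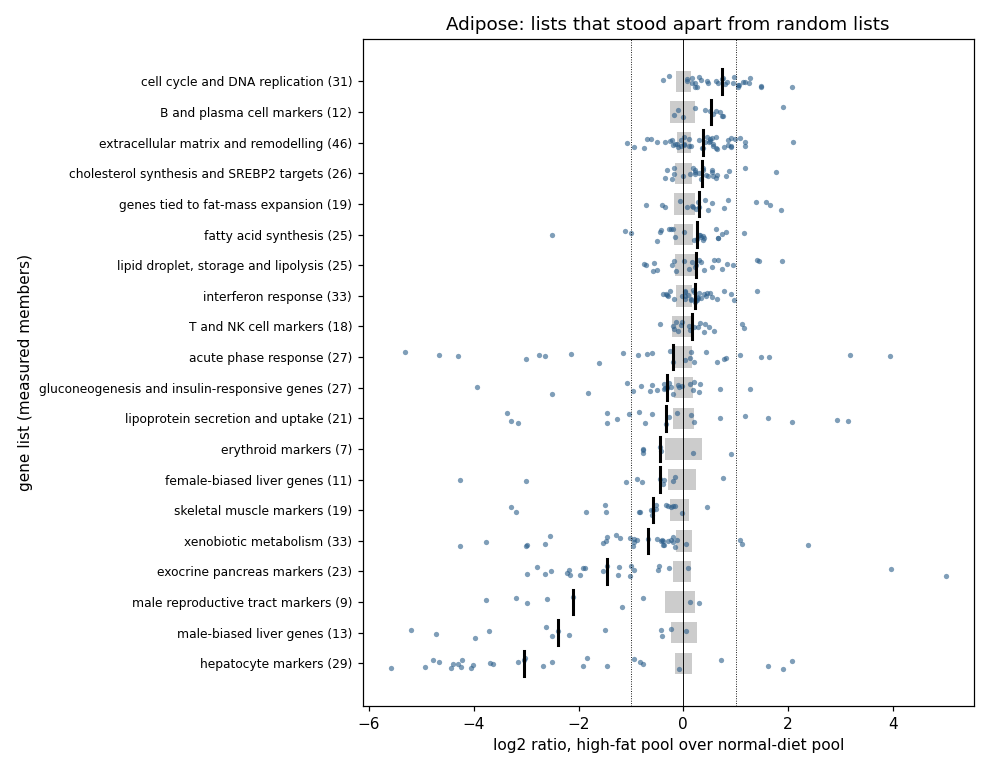
Log2 ratio of the high-fat over the normal-diet adipose pool (x axis) for each measured member (points) of the gene lists that stood apart (y axis, number of measured members in brackets), with the list's median (black bar), the middle 95% of medians of random lists (grey) and 2-fold (dotted lines). Hepatocyte markers (median -3.04), male-biased liver genes (-2.39) and male reproductive tract markers (-2.10) lie farthest below 0, and cell cycle genes (0.75) farthest above.

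The adipose counts depend on the normalization too. With median centring 4208 genes were higher and 616 lower (87.2% of the 2-fold genes higher, against 45.1%), and the median of all measured genes was 0.69. Here too a dye difference that changes with brightness stays in the centred ratios. The lipoprotein, drug metabolism, gluconeogenesis, acute phase and erythroid medians then lay above 0. The calls for fatty acid synthesis (percentile 88.4), cholesterol synthesis (81.0), lipoproteins (4.81), gluconeogenesis (2.76), interferon (97.3), T and NK cells (83.1) and erythroid cells (4.64) ended, while acute phase genes lay at 95.5. The count of lower genes was 1230 with the software's log ratio, and without genes of other tissues 483 genes were higher and 520 lower.

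The same diet contrast was set side by side in both tissues over the 12689 genes measured on both arrays. Few genes differed in both. Across genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.09 and a Spearman rho of 0.13, and a dye bias shared by both arrays would add to these. In all, 18 genes were at least 2-fold apart the same way, where 4.63 would be shared by independent lists. Of these, 6 were higher in both (2.07 for independent lists) and 12 lower (2.56). Genes of the same family or tissue, among them Cyp3a and muscle genes, count separately here. The excess is therefore not a measure of a shared effect of the diet. Without genes of other tissues, 9 were apart the same way. Dmbt1 (2.98 in liver, 2.66 in adipose tissue), Tff3 (2.40 and 3.95), Saa2 (2.19 and 3.95) and Saa1 (1.90 and 3.18) were higher in both pools. Cyp3a16 (-2.17 and -4.26), Cyp3a11 (-2.02 and -3.76) and the muscle genes Myh4 (-1.60 and -3.19) and Tnni2 (-1.59 and -1.49) were lower in both. Another 10 genes were at least 2-fold apart in opposite ways, where 4.60 would be shared by independent lists, 5 higher in liver and lower in adipose tissue and 5 the reverse. Akr1c6 (1.22 in liver, -4.26 in adipose tissue), Mup2 (1.26 and -3.47), Apoa2 (1.14 and -3.16), Mup19 (1.12 and -3.15) and Gpcpd1 (1.05 and -1.20) were higher in liver. Apoa2 is among the brightest genes of the liver array, whose ratios leaned upward whatever their kind. Slc39a4, an intestinal zinc transporter (-1.04 and 2.02), Ces2a (-1.18 and 1.18) and Prxl2b (-1.11 and 1.09) were higher in adipose tissue. Hepatocyte markers moved with the first of these groups (0.38 and -3.04) and skeletal muscle markers were lower in both tissues (-1.10 and -0.58).

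**Figure D4:**
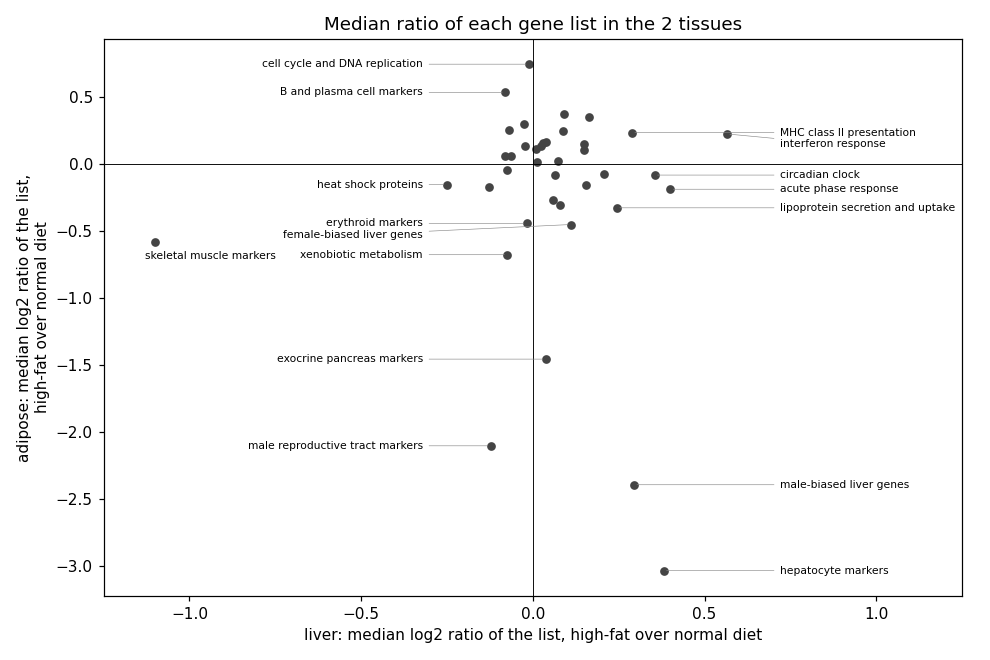
Median log2 ratio of each gene list, high-fat over normal diet, in liver (x axis) and in adipose tissue (y axis), with a point per list that had at least 5 measured members in both tissues and names for those farthest from 0. Hepatocyte markers (0.38 in liver, -3.04 in adipose tissue) and male-biased liver genes (0.29, -2.39) lie on opposite sides of 0, and skeletal muscle markers (-1.10, -0.58) below 0 in both.

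The number of genes apart the same way was 55 with the software's log ratio, 29 with an offset of 10, 225 with median centring and 9 without genes of other tissues. The numbers that independent lists would share were not computed for the alternatives. Genes apart in opposite ways numbered 60 with median centring, 5 without genes of other tissues and 5 with the running median subtracted, and r was 0.20 with median centring, 0.18 over genes past 2 times the scanner error and 0.033 with local backgrounds as deposited.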

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

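The tests of liver RNA in the adipose pool and of a dye bias of the liver genes were chosen only after the result was seen, while the intestine tests and the brightness test were set before their values were. The differences between liver and adipose tissue given here were not tested, since each tissue has 1 array.

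Many genes of liver were far lower, and most measured markers of small intestine far higher, in the high-fat adipose pool. A dye bias of the probes is argued against by the same probes with the same dyes on the liver array, where hepatocyte markers had a median log2 ratio of 0.38 and the 20 measured intestine markers 0.074. RNA of liver in the normal-diet adipose pool remains a candidate source: of 173 genes at least 16-fold brighter on the liver array than in either adipose channel, with all listed or rule-named genes left out, 51.4% were at least 2-fold lower in the high-fat adipose pool, just over the 50% set as the limit (55.6% of 266 in a first form of the test that used the mean of the adipose channels and left out the hepatocyte list alone), against 2.51% of 11669 other genes, and hepatocyte markers stood at a median of 4.94% of their liver level in the normal-diet pool and 0.663% in the high-fat pool. RNA of small intestine in the high-fat adipose pool remains one too: the 47 intestine markers, none of them in the lists fixed at the start, had a median of 3.24 over 38 measured, with Anpep (1.70), Lgals4 (3.64), Lyz1 (1.73) and Lgals2 (2.64) the brightest, although Anpep and Lyz1 are made outside the gut as well. An effect of the diet on these genes within fat stays open as untested, and the sources of the pancreas, muscle and reproductive tract genes were not tested.

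In liver, abundant hepatocyte genes were slightly higher in the high-fat pool (median 0.38). A dye difference at high brightness that loess left behind may account for part or all of this. Equally bright genes that are not brighter on the liver array had a median of 0.18, against 0.36 for the 26 hepatocyte markers they were matched to. That is 49.8%, just under the 50% set as the limit for such a cause and over the 25% set against it. The hepatocyte median was 0.04 with the software's log ratio and 0.004 with the running median by brightness subtracted. Liver-enriched genes themselves shape that running median, with 69 of them against 46 others at a mean log2 intensity of 16 or more. The diet and this dye difference cannot be told apart for these genes without a dye swap.

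Several results went opposite ways in the 2 tissues. The median of lipoprotein genes was 0.24 in liver and -0.33 in adipose tissue, that of male-biased liver genes 0.29 and -2.39, that of acute phase genes 0.40 and -0.19, and that of hepatocyte markers 0.38 and -3.04. The adipose direction of the acute phase genes is not settled. They lay at percentile 95.5 with median centring and no longer stood apart with the software's log ratio (4.55) or an offset of 10 (5.83). Without genes of other tissues the 17 members left had a median of 0.44, but that turn is partly built in, since mostly lower members were taken out. Lipoprotein genes in adipose tissue no longer stood apart with median centring (4.81). In liver, hepatocyte and male-biased genes no longer did with the software's log ratio (66.9 and 83.4), where their medians were 0.04 and 0.07. With the running median by brightness subtracted they did not either (52.1 and 91.1), at medians of 0.004 and 0.08. The log2 ratio in liver minus that in adipose tissue was 5.48 for Akr1c6, 4.73 for Mup2, 4.30 for Apoa2, 4.27 for Mup19, 2.25 for Gpcpd1, -2.20 for Prxl2b, -2.36 for Ces2a and -3.06 for Slc39a4. It was -2.65 for AA986860 and -4.25 for Gm3776, which the naming rule leaves out and which were chosen after their values were seen.

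On the adipose array an E1A control probe, which is outside the comparisons, had a median signal of 356 in the normal-diet channel and 536.5 in the high-fat channel over 32 spots. The 153 negative control spots had medians of 52 and 54 and highest signals of 84 and 191. An ERCC control probe had a median of 101.75 over 10 spots in the high-fat channel, below that highest signal of 191. On the liver array no E1A or ERCC probe was well above background at all of its spots. Per the labels, control targets were added at hybridization.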

How the results depend on the processing

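The alternatives with local backgrounds as deposited, without genes of other tissues and with the running median subtracted were chosen after seeing the data, the first because the liver fit fixed at the start was distorted by a few extreme local backgrounds. Of 39 list results that stood apart, 14 did so the same way in every alternative that gave a value, and of 39 that did not, 23 never did. The lists of the interferon response, MHC class II, clock, immediate early, cholesterol synthesis, drug metabolism and skeletal muscle genes in liver, and of cell cycle, hepatocyte, male-biased liver, drug metabolism, exocrine pancreas, skeletal muscle and male reproductive tract genes in adipose tissue, are those 14. Leaving out saturated spots changed nothing, because no spot was saturated. No paired analysis applies to pools. Values below are counts, correlations or percentiles among random lists, and the cause was not tested in any of them. Signal over background limits the dim genes: 14720 probes in liver and 11530 in adipose tissue were above background in neither channel, and the offset of 50 pulls dim ratios toward 0.

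With the software's log ratio, 138 genes were higher and 157 lower in liver, 1230 lower in adipose tissue and 55 apart the same way in both. In liver, hepatocyte markers (66.9), male-biased genes (83.4), bile acid genes (89.2) and matrix (96.2) no longer stood apart, while lipid droplets (99.3), inflammatory mediators (99.8) and B and plasma cells (0.26) did. In adipose tissue, acute phase genes (4.55) no longer did and thermogenic genes (2.02) did.

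Without background subtraction, genes tied to fat-mass expansion (1.33) and B and plasma cells (0.33) stood apart in liver. With an offset of 10, 29 genes were apart the same way, and in adipose tissue acute phase genes (5.83) no longer stood apart while thermogenic genes (2.47) did.

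With median centring, 445 genes were higher and 28 lower in liver, 4208 higher in adipose tissue, 225 apart the same way and 60 in opposite ways, and r was 0.20. The median of all measured genes was then 0.32 in liver and 0.69 in adipose tissue. Median centring leaves in a dye difference that changes with brightness. In liver, NRF2 targets (31.3) and matrix (86.3) no longer stood apart, while lipid droplets (98.1), adipocytes (1.22), B and plasma cells (0.915) and the male reproductive tract (0.78) did. In adipose tissue, fatty acid synthesis (88.4), cholesterol synthesis (81.0), lipoproteins (4.81), gluconeogenesis (2.76), interferon (97.3), T and NK cells (83.1) and erythroid cells (4.64) no longer did, acute phase genes moved to the other side (95.5), and the clock (1.05), thermogenic genes (0.24) and macrophages (98.1) stood apart. Gadd45g in adipose tissue turned from -1.09 to 0.10, and was the only gene past 2-fold among those named by the rule to change sign in any alternative.

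With probes above background in at least 1 channel, 116 genes were higher in liver. Adipocytes (97.6) and B and plasma cells (1.42) then stood apart in liver, and bile acid genes (1.4), inflammatory mediators (98.6) and granulocytes and mast cells (0.84) in adipose tissue. Without a filter on dim probes, 103 genes were higher in liver, where NRF2 targets (3.35), matrix (71.1) and thermogenic genes (7.4) no longer stood apart and B and plasma cells (0.265) did. In adipose tissue, T and NK cells (93.4) and erythroid cells (9.15) no longer did, while bile acid genes (0.38), inflammatory mediators (99.3) and granulocytes and mast cells (2.47) did.

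With the brightest probe per gene, ribosomal proteins in liver (3.85) no longer stood apart, while endothelium in liver (0.96) and macrophages in adipose tissue (97.7) did.

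Over genes past 2 times the scanner error, r was 0.18. Lists with fewer than 5 such members gave no value, which left 57 of 78 results. In liver, fatty acid oxidation (67.3), lipoproteins (78.8), NRF2 targets (29.6), male-biased genes (84.5), acute phase (79.6), heat shock proteins (5.2) and macrophages (73.2) no longer stood apart, bile acid genes (35.4) and hepatocyte markers (47.4) moved to the other side of the middle, and gluconeogenesis (2.31) stood apart. In adipose tissue, fatty acid synthesis (94.4), cholesterol synthesis (96.1), lipid droplets (90.7), female-biased liver genes (3.64), interferon (92.0), matrix (96.9), fat-mass expansion (96.6), B and plasma cells (97.1) and erythroid cells (6.84) no longer did, while thermogenic genes (1.2) did. This alternative selects on the ratio itself and leaves fewer genes per list, and medians of most of these lists were farther from 0 (0.54 for fatty acid oxidation in liver, 0.56 for matrix in adipose tissue), so an ended call does not show a smaller shift.

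With local backgrounds as deposited, 20 genes were higher and 35 lower in liver and r was 0.033. Heat shock proteins in liver (8.77) no longer stood apart, while lipid droplets (97.8), female-biased genes (98.6), oxidative phosphorylation (2.47) and endothelium (1.53) did.

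Without genes of other tissues, 9 genes were apart the same way and 5 in opposite ways. Lipid droplets in liver (98.2) and bile acid genes in adipose tissue (99.98) then stood apart, and acute phase genes in adipose tissue turned to 99.98. The adipose bile acid value rests on the 5 members that remained and the acute phase value on 17, and leaving out genes that liver expresses takes out mostly members that were lower, so both turns are partly built in.

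With the running median by brightness subtracted, 5 genes were apart in opposite ways. In liver, bile acid genes (82.9), male-biased genes (91.1), matrix (94.7) and hepatocyte markers (52.1) no longer stood apart, while female-biased genes (97.8) did.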

Other observations

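The tests of collection time and of dye bias for the clock genes, and the tests of glucocorticoid-responsive genes, were chosen only after the result or part of it was seen, and every gene named here outside the naming rule was chosen after its values were.

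Beyond the 8 genes that the rule names for both tissues together, 10 more were at least 2-fold apart the same way in both tissues. Reg3b (1.35 in liver and 6.36 in adipose tissue) and Clec2h (1.00 and 2.79) were higher in both. Lower in both were the B cell chemokine Cxcl13 (-1.12 and -1.14), the fatty acid elongase Elovl3 (-1.39 and -2.51), Pdk4 (-1.48 and -1.08), Cyp3a59 (-1.30 and -1.92), Zbtb16 (-2.73 and -1.41) and the muscle genes Pgam2 (-1.21 and -2.70), Tnnc2 (-1.48 and -3.29) and Tnnt3 (-1.47 and -1.48). In liver the cytokine-signalling inhibitors Cish and Socs2 were higher (2.13 and 1.31), and they stood at -0.07 and 0.58 in adipose tissue.

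Clock genes of opposite phase were opposite in the liver pools: the 8 genes of the Dbp phase had a median of 1.07 and the 3 of the Arntl phase -0.92, a gap of 2.00. A dye bias of the probes is argued against by adipose tissue, where the 8 clock genes past 2-fold in liver had 11.4% of their liver ratio in the median. A difference in the time of day at collection may account for the pattern, but the gap in adipose tissue was 0.61, 30.4% of that in liver, between the 25% and 50% set as limits, and too few genes, 3 in the Arntl phase, decide it. That gap rests on Clock (-0.55) and Nfil3 (-0.59), while Arntl itself was at 0.22 in adipose tissue, opposite to liver, and the Dbp phase had a median of 0.06 with 4 of 8 genes below 0. An effect of the diet on the liver clock stays open as untested, and it and the time of collection cannot be told apart for these genes.

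Lower glucocorticoid signalling in the high-fat group is a hypothesis drawn from genes that respond to glucocorticoids: Zbtb16, Tsc22d3 (-1.29 in liver and -0.93 in adipose tissue) and Ddit4 (-1.61 and -0.98) were lower, while Fkbp5 was lower in adipose tissue (-1.44) and at -0.16 in liver. A list of 16 such genes had a median of -0.22 over 15 measured in liver and -0.62 over 14 in adipose tissue, below all 10000 random lists in both. Values of Dusp1, Nfkbia and Gadd45b on that list had been seen before it was written, so the test was restricted to members outside the lists fixed at the start. In liver the 11 such members had a median of -0.11 at percentile 3.27, with 7 below 0 and none past 2-fold, which decides nothing. In adipose tissue the 11 had a median of -0.82 at percentile 0, with 8 below 0 and 4 at least 2-fold lower (Mfsd2a -2.23, Klf15 -1.45, Arrdc2 -1.16, Cebpd -1.001), which is consistent with the hypothesis there. Of these adipose members, Sgk1 (0.15), Rasd1 (0.45) and Cdc42ep3 (0.18) were above 0. RNA of other tissues in the adipose pools was not excluded as a source of the adipose shift. A different time of day at collection was not excluded in either tissue, and hormone levels were not analysed here.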
